A study of Mus musculus with 24 samples.

How the data were processed

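RNA of epidermis peeled from the dermis after trypsin was hybridized to Illumina BeadChip arrays, 1 array per sample, 24 arrays on 8 chips, per the labels. The deposited scanner file held an average bead signal (intensity) per probe and array, not normalized between arrays. In 4 of the arrays, those of the 2 chips called G and H here, a background level was already subtracted from the deposited intensity, as values below 0 showed. Per the file headers, a detection p-value follows each intensity column. The values showed that 10 of these columns held the detection p-value and 13 deposited columns held the fraction 1 minus that p-value. One column, of adult sample 3, held bead numbers per the last line of the file, and this 1 per-sample column was not used. The deposited matrix held log2 values normalized by the authors with limma, per the submitters' processing notes. Its column medians were 7.47 for each of the 20 arrays of P3 to P20, and 9.59, 9.56, 9.54 and 9.68 for adult samples 1 to 4, which held values for 1977 probes. Ranks of the deposited matrix and the scanner intensity matched within each array (Spearman correlation at least 0.999995 where both held values).

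The intensities were background-corrected by the normal-exponential model with background estimated from the detection p-values, offset by 16, quantile-normalized and put on the log2 scale (R 4.3.3, limma 3.58.1). For the array without detection p-values the background was taken from the other arrays of its chip, relative to the 10th percentile of each. Of 45281 probes with 30854 distinct names, 27760 were matched to a current gene symbol directly and 7994 through a synonym, 9318 kept the name in the file, 187 had an ambiguous synonym and 22 several names. Probes with a detection p under 0.01 in at least 2 arrays were kept (20739, of which 20737 had 1 name), and each gene was given its probe with the highest mean, which left 14392 genes. Per array, the 75th percentile of the signal lay 21.2 to 182 units above background, and low signal limits what can be said of dim genes. Members of the Krtap, Sprr, Lce and Serpinb3 families are similar in sequence, and cross-hybridization between them was not tested. Saturation was looked for after the results were seen. The highest signal of an array ran from 30371 to 70117.5, and no array had equal values among its 50 brightest probes. Stfa1 and Stfa2 in P6 mutants, Stfa1 in P13 mutants, Krt27 in P13 controls and Krt27 and Krt71 in the adult control lay above 0.9 of the highest signal in every array of the group. Krt33a in P13 controls lay at 0.691 and 0.861 of it. Compression of the brightest signals was not tested, and it would make differences of such genes too small. No pair of arrays was a copy: the smallest SD of the log2 difference between 2 arrays was 0.317.

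Before the data were examined, the groups, contrasts, main fit, alternative settings, gene lists and the rule for named genes were fixed. Arrays were grouped by age and genotype. The P3 array with conflicting labels entered no contrast but had its own group in the fit. A linear model with 1 mean per group was fitted with limma to all 24 arrays (12 residual and 4.12 prior degrees of freedom), with moderated statistics and p-values adjusted by Benjamini and Hochberg over all genes tested in each contrast, at 0.05. The contrasts were mutants minus controls at P3, P6, P13 and P20, the mean of the last 3, this mean minus the P3 effect, all pairs of ages, and in adults the 3 mutants minus the Mad2f/+ control and the p53f/+ mutants minus the mutant without that allele. Controls were compared across ages by a moderated F test. The 36 lists of cell types, pathways and stress responses were written from general knowledge before the files were read, and those with at least 5 genes were tested with camera at a preset correlation of 0.01, adjusted over the lists of a contrast, and again with an estimated correlation and with fry. One list symbol, Rod1, now names another gene and was left out. Named genes were Mad2l1, then in each contrast, among genes past the threshold whose arrays did not overlap between the sides, the 8 largest rises and 8 largest falls, and for each list past camera or with at least 3 members past the threshold, up to 4 members with the largest changes. Genes named outside this rule were chosen after their values were seen: Trp53 as the second targeted gene, the genes shared by all 4 ages, and the group means of Krt33a, Krt15 and Cd3e in controls.

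The alternative settings fixed beforehand were no background correction, the authors' normalized values, an offset of 50, no filter or detection in at least 12 arrays, the mean of a gene's probes or every probe alone, the chip as a fixed or a random block, only chips that hold both sides, only the compared groups, the conflicting array as a mutant or a control, array weights, trended and robust moderation, sex-linked genes left out, and each array left out in turn. Added after the data were seen were the fibroblast list mean as a covariate, sex by Xist as a covariate, the fit without chips G and H, each P20 chip alone, and the alternatives for pairs of ages. The scripts were tested on simulated data (seed 42, 14390 genes, 67, 67 and 66 of them changed 2-fold, 4-fold and 16-fold). Each gene was given the spread pooled over all groups, the same in every array. At 4-fold, 86.6% of the changed genes were recovered at P3, 74.6% at P6, 76.1% at P13, 82.1% at P20, 100% in the mean of P6 to P20, 65.7% in its difference from P3, 68.7% for the adult Mad2 and 59.7% for the adult p53 comparison, and 77.6% over the control ages. At 2-fold the shares were 14.9% at P3, 5.97% at P6, 17.9% at P13, 11.9% at P20, 73.1% in the mean of P6 to P20, 10.4% in its difference from P3, 7.46% for the adult Mad2 and 2.99% for the adult p53 comparison, and 5.97% over the control ages. None had the wrong direction, and 5 to 11 unchanged genes were called per comparison. Of the simulated lists, 1 was shifted and was called in each of the 8 comparisons, with camera at either correlation and with fry. Of the 35 unshifted lists, camera at the preset correlation called 2 and fry 4 at P13, and none in the other comparisons. Camera with an estimated correlation called none. The simulated genes and arrays were drawn independently, with no correlation between genes or within a chip. Real P20 arrays of a group on different chips differed more than those of a group at P3, P6 or P13. The simulated ones did not, so the P20 rates may be too high. These rates therefore need not hold for the real arrays.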

Results

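Gene expression was measured in mouse epidermis on Illumina BeadChip arrays, glass chips that carry several arrays of bead-bound probes, in 24 samples. The mice carried floxed alleles of Mad2, whose gene is Mad2l1 and whose protein is a core part of the spindle assembly checkpoint that holds cells in mitosis until their chromosomes are attached. Mutants (Mad2f/f; K14-Cre) expressed Cre recombinase from the promoter of Krt14, a keratin of basal keratinocytes, and controls carried no Cre. Mutants and controls were compared at postnatal day 3 (P3, 2 mutant and 4 control samples), P6 (2 and 2), P13 (2 and 2) and P20 (2 and 3). The labels record no phenotype in mutants at P3 and call the mutants from P6 on nude, that is, hairless. A set of 4 adult samples held 1 mutant, 2 mutants that also carried a floxed allele of the tumour suppressor gene Trp53 (p53f/+), and 1 Cre-positive control with a single floxed Mad2 allele (Mad2f/+). One further P3 array had conflicting labels, a mutant genotype but the sample type of a control, and entered neither group. The 75th percentile of the signal lay 21.2 to 182 intensity units above background per array, and 23.3% to 40.1% of the 45281 probes were detected. The number of arrays limits the precision of every value. The labels list the samples separately but do not say that each came from a separate animal. The p-values therefore rest on the spread between these samples, which may in part be technical. That spread was pooled over all groups into 1 estimate per gene, so it is not the spread of any 1 age. Fold changes below are on the log2 scale with their standard error (SE), and a gene "rose" or "fell" where its adjusted p was under 0.05.

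Mad2l1 was lower in the mutants at every age. Its normalized log2 intensity averaged 5.28 ± 0.69 (SD, n = 2) in P3 mutants against 7.42 ± 0.41 (SD, n = 4) in P3 controls. At P6 the averages were 6.10 ± 0.25 in mutants and 8.29 ± 0.41 in controls (SD, n = 2 each). At P13 they were 5.09 ± 0.27 and 8.78 ± 0.86 (SD, n = 2 each). P20 mutants averaged 4.99 ± 0.50 (SD, n = 2) against 7.06 ± 0.62 (SD, n = 3) in controls. The differences were -2.14 ± 0.40 (SE, adjusted p = 0.00629) at P3, -2.20 ± 0.47 (adjusted p = 0.00261) at P6. They were -3.69 ± 0.47 (adjusted p = 3.84e-05) at P13 and -2.06 ± 0.43 (adjusted p = 0.0053) at P20. The probe was not detected above background in the mutants at P3, P13 and P20. The fold at these ages is given as a lower limit, the mean of the bright group against the higher of the dim value and the lowest detected signal of each array: at least 2.52-fold, at least 7.89-fold and at least 1.78-fold. The adult mutants, with and without the Trp53 allele, lay between 4.78 and 4.86, none above background, against 7.98 in the adult Mad2f/+ control. A dimmer Mad2l1 probe fell at P6, P13 and in adults. It was not detected in any P3 or P20 array, controls included, so it checks nothing at those ages. The positions of both probes relative to the deleted exons were not given in the sources used here, so they need not report the deletion itself. The brighter probe kept its sign in every setting and was no longer past the threshold in several. At P3 and P20 this was so in the authors' normalized values (-0.72, adjusted p = 0.131, and -0.64, adjusted p = 0.0714). At P3 it was so without mutant sample 1 (-1.66, adjusted p = 0.184) and with the conflicting array as a mutant (-1.34, adjusted p = 0.479), and at P6 within the chip (-1.91, adjusted p = 0.0626). At P20 it was so with only P20 arrays (-2.06, adjusted p = 0.198), with array weights (-2.36, 0.136) and without mutant sample 1 (-1.71, 0.0502), and in adults with only adult arrays (-3.16, 0.058). In settings added after the data were seen, the P20 call ended with sex as a covariate (-2.08, adjusted p = 0.0578), without chips G and H (-1.71, 0.112) and on chip F alone (-1.71, 0.121). The P6 and adult calls ended with the fibroblast covariate (-3.90, adjusted p = 0.249, and -4.52, adjusted p = 0.125). Where a fit to only the compared groups, array weights or a covariate ended a call, the fall itself was no smaller.

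**Figure D1:**
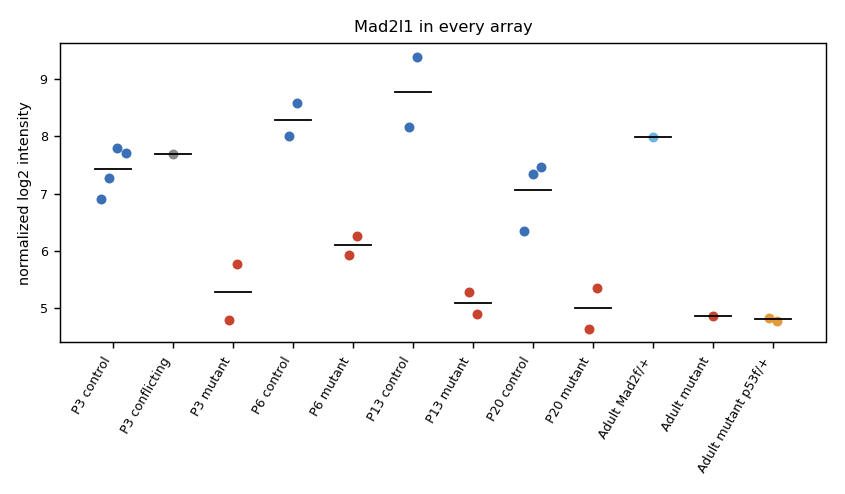
Normalized log2 intensity of the brighter Mad2l1 probe in each of the 24 arrays (points, vertical axis) by group (horizontal axis), with the group mean as a line. Mutant arrays lie between 4.64 and 6.27 and control arrays between 6.35 and 9.39.

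The P3 comparison asked what differed in mutant epidermis at an age without recorded phenotype (2 mutant against 4 control samples). Genes of the hair fibre were already lower. The hair shaft keratin list also holds genes that are not keratins, such as S100a3 and Psors1c2. Of its 17 genes, called hair shaft keratins below, 14 fell and 3 did not pass the test (16 fell when adjusted over the list alone). The cortex keratins were among them: Krt31 (-4.53 ± 0.41), Krt33a (-4.15 ± 0.46), Krt33b (-4.14 ± 0.69) and Krt81 (-3.97 ± 0.65). Of 27 keratin-associated protein genes, whose products cross-link hair keratin filaments, 23 fell (24 adjusted over the list alone). Krtap19-4 was at -6.61 ± 0.40, Krtap6-2 at -5.21 ± 0.59 and Krtap16-3 at -5.06 ± 0.74. In the inner root sheath list, the layer that moulds the growing hair, 6 of 14 genes fell (10 adjusted over the list alone). These included the keratins Krt26 (-4.12 ± 0.40), Krt72 (-3.81 ± 0.28) and Krt28 (-3.12 ± 0.60). The hair matrix list had 3 of 21 genes lower (11 adjusted over the list alone): Cux1, a transcription factor of the inner root sheath, at -1.41 ± 0.35, the Wnt inhibitor Nkd1, at least 3.88-fold lower, and Foxn1, the transcription factor lost in the classical nude mouse, at least 1.03-fold lower. These 4 lists were lower by camera (adjusted p = 2.84e-44, 9.09e-77, 4.96e-20 and 1.32e-07) and kept the call with an estimated correlation.

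A small set of genes was higher at P3. Of 30 p53 target genes, 4 rose and none fell (5 rose adjusted over the list alone): Ccng1 (1.64 ± 0.28), the pro-apoptotic genes Bbc3 (1.36 ± 0.33) and Apaf1 (1.35 ± 0.33), and Ddit4l, at least 2.63-fold higher. This list was higher by camera with the preset correlation (adjusted p = 1.9e-07) and with an estimated one. Of 28 genes induced in wounded and hyperproliferative epidermis, 3 rose (4 adjusted over the list alone): the protease inhibitor Serpinb3c (4.25 ± 0.48), Krt16 (2.81 ± 0.48), a keratin of activated keratinocytes, and the cornified envelope gene Sprr2d (2.77 ± 0.60). This list was higher by camera (adjusted p = 7.23e-05; adjusted p = 0.548 with an estimated correlation). Outside the lists, Fetub, a fetuin, was at least 7.14-fold higher and Serpine2, a serine protease inhibitor, rose by 3.02 ± 0.45. The mitosis and DNA replication lists were higher by camera (adjusted p = 0.0171 and 0.0318) with none of their 18 and 27 genes past the threshold. Neither call held with an estimated correlation (adjusted p = 0.956 and 0.877). Lists of other cell types moved too: the fibroblast list was higher by camera (mean difference 0.57 ± 0.32; 1 of 21 genes rose, Col6a3 at 2.45 ± 0.61), as was the myeloid list (1 of 18 rose, C1qb at 2.62 ± 0.61). The hair follicle stem cell list (Sox9 fell) and sebaceous gland list (Mc5r, at least 2.16-fold lower) were lower. None of these 4 calls held with an estimated correlation (adjusted p = 0.548, 0.877, 0.426 and 0.548).

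In all, 277 of 14392 genes passed the threshold at P3, 40 higher and 237 lower, and 1128 had an unadjusted p under 0.05. With the chip as a fixed block the count was 421, as a random block 436 and within the chip that holds both groups 242. Without P3 mutant sample 2 it was 139, and with the array of conflicting labels counted as a mutant 70. It was 456 with array weights and, in a setting added after the data were seen, 514 without chips G and H. Of the 34 named genes past the threshold at P3, 6 stayed past it with the conflicting array as a mutant and 30 with it as a control. The Mad2l1 log2 intensity of that array, 7.69, lay within the range of the P3 controls (6.91 to 7.80) and above both mutants (4.80 and 5.76). Of the 36 lists, 12 passed (13 with the chip block, 12 within the chip).

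At P6, the first age with the hairless label (2 mutant against 2 control samples), genes of stressed and differentiating keratinocytes were higher and genes of the hair follicle lower in mutants. Of the 28 wound and hyperproliferation genes, 21 rose and none fell (23 rose adjusted over the list alone): Sprr2d (8.41 ± 0.70), the alarmin gene S100a9 (6.52 ± 1.03), the stress keratin Krt6b (6.31 ± 0.80) and Serpinb3c, at least 109-fold higher. Among 34 genes of the spinous and granular layers 22 rose (26 adjusted over the list alone). The cornified envelope genes among them included Rptn at 5.91 ± 0.72, Lce1g at 4.59 ± 0.92 and Lce1i at 4.17 ± 0.97. Of 24 lipid barrier genes 15 rose (18 adjusted over the list alone), such as the lipoxygenase Alox12b (3.48 ± 0.36), the ceramide synthase Cers3 (2.94 ± 0.29) and Degs2, at least 16.3-fold higher. Cytokine and chemokine genes (13 of 23 rose, 1 fell; 14 and 1 adjusted over the list alone) included Il33 (4.85 ± 0.84) and Il18 (3.76 ± 0.73). Interferon response genes (14 of 23 rose; 19 adjusted over the list alone) included Oasl2 (3.78 ± 0.98) and Usp18 (3.53 ± 0.83). Antigen presentation genes of Langerhans cells (10 of 13 rose) included Cd207 (2.88 ± 0.79) and H2-Eb1 (2.71 ± 0.63). Camera placed the lists higher (adjusted p = 2.56e-17 for wound, 8.31e-14 for spinous and granular, 7.11e-12 for lipid barrier, 4.61e-07 for cytokines, 2.16e-08 for interferon and 2.71e-05 for Langerhans). The lipid barrier call held with an estimated correlation, and the others did not (adjusted p = 0.0659, 0.0659, 0.0659, 0.243 and 0.243).

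Hair shaft keratins fell in 12 of 17 genes (14 adjusted over the list alone), with Krt35 at -4.09 ± 0.69 and Krt31 at -3.83 ± 0.47. Keratin-associated proteins fell in 12 of 27 (Krtap19-4 at -4.51 ± 0.46) with 1 higher, and inner root sheath genes fell in 7 of 14 with 1 higher. Of 21 hair matrix genes 16 fell (19 adjusted over the list alone), including the signalling genes Shh (-3.31 ± 0.52) and Wnt5a (-3.30 ± 0.78) and the hair keratin regulator Hoxc13 (-3.19 ± 0.55). Of 17 hair follicle stem cell genes 11 fell and 1 rose, including Krt15 (-3.53 ± 0.81) and Tbx1 (-4.19 ± 0.49). By camera these lists were lower (adjusted p = 1.88e-07, 0.00037, 0.00508, 1.81e-09 and 5.89e-05). The hair matrix call held with an estimated correlation, and the other 4 did not (adjusted p = 0.0908, 0.328, 0.248 and 0.0908). Cell division genes were lower: 12 of 18 mitosis genes (15 adjusted over the list alone), such as Mki67 (-2.58 ± 0.71) and Kif2c (-2.24 ± 0.76). So were 10 of 27 replication genes, such as Uhrf1 (-2.84 ± 0.39) and Tk1 (-2.55 ± 0.59), 6 of 20 DNA repair genes, such as Blm (-1.94 ± 0.57). The checkpoint list had 6 of 17 genes lower (1 rose), among them Mad2l1 itself, Incenp (-2.16 ± 0.66) and Cdc20 (-1.78 ± 0.62). Their camera calls (adjusted p = 2.61e-06, 5.45e-05, 0.00254 and 0.00976) were lost with an estimated correlation (adjusted p = 0.248, 0.243, 0.243 and 0.267). Of 30 p53 targets 10 rose and none fell (the same count adjusted over the list alone), such as Pmaip1 (2.21 ± 0.51), Polk (1.75 ± 0.47) and Ccng1 (1.68 ± 0.33). The list had a camera call (adjusted p = 0.00153) that was lost with an estimated correlation (adjusted p = 0.0908).

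Genes of dermal cell types were much lower in the P6 mutants. Of 21 fibroblast genes 19 fell (the same count adjusted over the list alone). The collagen genes Col1a1 and Col6a1 were at least 150.3-fold and at least 95.5-fold lower, and Decorin (Dcn) was at -7.34 ± 0.89. Of 14 endothelial and blood genes 12 fell, with the haemoglobin gene Hba-a1 at -6.11 ± 1.13. Mean list differences were -4.45 ± 0.37 for fibroblasts and -3.42 ± 0.48 for endothelium and blood. The 2 control samples carried far more of these transcripts than the 2 mutant samples, beside every gene group above. The melanocyte (7 of 14 fell, Mlana at -3.41 ± 0.51), muscle (5 of 15 fell, Acta2 at -3.65 ± 0.61), nerve (5 of 8 fell and 1 rose, Pmp22 at -4.08 ± 1.01) and ribosomal protein lists (4 of 40 fell) were lower by camera. The sebaceous (5 of 14 rose, Fabp5 at 2.97 ± 1.02), cholesterol synthesis (6 of 20 rose and 1 fell, Dhcr7 at 1.95 ± 0.40), unfolded protein response (4 of 19 rose, Trib3 at 3.22 ± 0.31), myeloid (6 of 18 rose and 1 fell, Tyrobp at 1.78 ± 0.49) and T and NK cell lists (1 of 13 rose and Thy1 fell, -2.49 ± 0.71) were higher. Of the dermal and later lists the fibroblast call held with an estimated correlation, whereas the endothelium list (adjusted p = 0.0659) and the other 9 (adjusted p = 0.243, 0.316, 0.243, 0.318, 0.389, 0.305, 0.0908, 0.393 and 0.391) did not.

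The P6 count was 3248 genes, 1351 higher and 1897 lower, and 27 of 36 lists. Leaving out any of the 4 arrays gave 1762 to 2092 genes. The count was 3500 with the chip as a fixed block and 3965 as a random block, 1704 within the chip that holds both groups, where the control is 1 array (28 lists with the block and within the chip). It was 6002 with only P6 arrays, 6546 with array weights, and, in settings added after the data were seen, 5574 without chips G and H and 69 with the fibroblast list mean as a covariate. With that covariate, which nearly coincides with genotype at P6, 7 of 136 named genes stayed past the threshold and 29 changed sign.

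At P13 (2 mutant against 2 control samples, all on 1 chip), hair fibre genes were lower and stress keratinocyte genes higher in mutants. Of 17 hair shaft keratin genes 15 fell (the same count adjusted over the list alone, with 1 higher), with Krt33a at -9.32 ± 0.53, Krt33b at -8.74 ± 0.79 and Krt31 at least 154-fold lower. Of 27 keratin-associated protein genes 23 fell (the same count adjusted over the list alone), with Krtap7-1 at least 682-fold and Krtap6-5 at least 198-fold lower. Of 14 inner root sheath genes 11 fell, with Krt72 at least 228-fold and Krt28 at least 261-fold lower and Krt73 at -7.91 ± 0.80. Hair matrix genes fell in 17 of 21 with 1 higher, among them Cux1 (-3.47 ± 0.40) and Hoxc13 (-3.29 ± 0.55), and Shh was at least 8.55-fold lower. The fibroblast list differed by -0.48 ± 0.37, with 2 of 21 genes higher, 3 lower and no camera call (adjusted p = 0.297). The 4 hair lists were lower by camera (adjusted p = 5.71e-18, 4e-28, 2.27e-11 and 1.5e-08) and kept the call with an estimated correlation. Of 17 hair follicle stem cell genes 5 fell, such as Krt15 (-3.50 ± 0.81) and Lgr5 (-1.83 ± 0.43). Of 14 melanocyte genes 5 fell, such as Gpnmb (-3.24 ± 0.66). Both lists had camera calls (adjusted p = 0.021 and 0.0108) that did not hold with an estimated correlation (adjusted p = 0.368 and 0.368).

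Wound and hyperproliferation genes rose in 19 of 28 (20 adjusted over the list alone), with Sprr2d at 9.22 ± 0.70, Sprr2e at 8.12 ± 0.59, Lce3f at least 328-fold higher and the defensin gene Defb14 at least 171-fold higher. Spinous and granular genes rose in 25 of 34 (Lce1f at 6.81 ± 1.05, Rptn at 5.64 ± 0.72) with 1 lower, and lipid barrier genes in 15 of 24 (Degs2 at 6.13 ± 0.85, Alox12b at 3.88 ± 0.36) with 2 lower. These 3 lists were higher by camera (adjusted p = 1.13e-18, 2.28e-16 and 1.08e-09), also with an estimated correlation. Cytokine genes (12 of 23 rose, 1 fell; Il33 at 5.10 ± 0.84, Lcn2 at 4.57 ± 0.64) and interferon genes (12 of 23 rose; Oas2 at 4.04 ± 0.89, Usp18 at 2.97 ± 0.83) were higher by camera (adjusted p = 4.23e-06 and 1.86e-06). So were myeloid genes (8 of 18 rose; Coro1a at 2.22 ± 0.49, C1qc at 2.07 ± 0.71) and Langerhans genes (1 of 13 rose; Cd86 at 2.31 ± 0.54) (adjusted p = 0.000121 and 0.00927). With an estimated correlation the 4 adjusted p values were 0.0887, 0.396, 0.368 and 0.482. The mitosis list (2 of 18 fell, Ccnb1 at -2.07 ± 0.45 and Kif11 at -1.92 ± 0.49) and the ribosomal protein list (5 of 40 fell, 1 rose) were lower by camera (adjusted p = 0.021 and 0.021; adjusted p = 0.659 and 0.482 with an estimated correlation). The p53 target list gave no call (adjusted p = 0.45): 4 of 30 rose, including Pmaip1 (1.56 ± 0.51), and 3 fell, including Ckap2 (-1.90 ± 0.59). The P13 count was 2913 genes, 1420 higher and 1493 lower, with 15 of 36 lists. It was 4494 with the chip as a fixed block, 4401 as a random block and 2565 within the chip (17 and 16 lists with the fixed block and within the chip). It fell by more than 1.5 times without P13 mutant sample 1 (1504), control sample 3 (1808) or control sample 4 (1361). It was 4894 with only P13 arrays, 5570 with array weights and, in a setting added after the data were seen, 5228 without chips G and H.

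At P20 (2 mutant against 3 control samples) stress keratinocyte genes were higher, follicle stem cell and T cell genes lower, and hair fibre genes were low in both genotypes. Of 28 wound and hyperproliferation genes 22 rose and none fell (24 adjusted over the list alone), with the stefin gene Stfa2 at 8.24 ± 0.42, Sprr2d at 7.91 ± 0.64, Lce3f at 6.92 ± 0.56 and Serpinb3a at 6.76 ± 0.50. Of 34 spinous and granular genes 11 rose and 2 fell, with Lce1g at 4.22 ± 0.84 and Krt1, the main spinous keratin, at 3.02 ± 0.39. Of 17 hair follicle stem cell genes 9 fell, led by Krt15 (-6.74 ± 0.74), followed by Ccn2 (-3.45 ± 0.51) and Sox9 (-2.38 ± 0.26). Of 13 T and NK cell genes 6 fell (10 adjusted over the list alone), among them the T cell receptor subunits Cd3g and Cd3e (-2.75 ± 0.49 for Cd3e). In contrast, 4 of 14 melanocyte genes rose (7 adjusted over the list alone), such as Ednrb (2.10 ± 0.49) and Kit (1.88 ± 0.51). The hair shaft keratin list had 4 of 17 genes lower and 1 higher with no camera call (adjusted p = 0.0688). Among these were Krt33a at -1.98 ± 0.49, S100a3 at -1.70 ± 0.48 and Krt32 at least 6.46-fold lower. The gene that rose, Psors1c2 at 4.28 ± 0.57, is not a keratin.

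Camera placed the wound (adjusted p = 3.3e-29), spinous and granular (1.56e-05), interferon (2.83e-05; 5 of 23 rose, Bst2 at 2.85 ± 0.58), and melanocyte lists (0.00024) higher. It also placed the cholesterol synthesis (adjusted p = 0.00224; 3 of 20 rose, Ebp at 1.38 ± 0.38), lipid barrier (0.00957; 5 of 24 rose and 1 fell, Degs2 at 4.42 ± 0.78), cytokine (0.0124; 3 of 23 rose and 1 fell, Vegfa at 2.90 ± 0.63) and respiratory chain lists (0.0244; 2 of 36 rose, Ndufa1 at 0.97 ± 0.27) higher. It placed the T and NK cell (adjusted p = 7.8e-07), follicle stem cell (8.64e-06), keratin-associated protein (0.00522; 1 of 27 fell, Krtap3-1, at least 2.73-fold lower) and fibroblast lists (0.0424; mean difference -0.69 ± 0.34; 2 of 21 fell and 1 rose, Dpp4 at 1.94 ± 0.22) lower. None of these 12 calls held with an estimated correlation, where the adjusted p was 0.0593 for wound, 0.52 for spinous and granular, 0.546 for interferon and lipid barrier, 0.32 for melanocytes, and 0.52 for cholesterol synthesis. It was 0.532 for cytokines, 0.32 for the respiratory chain, 0.32 for T and NK cells, 0.213 for follicle stem cells and 0.632 for keratin-associated proteins and fibroblasts. By the X-linked RNA Xist, both P20 mutants read as female (9.58 and 9.34) and the 3 controls as male (at most 4.62), so sex and genotype coincided at this age. Sex was unbalanced in part elsewhere. At P3 Xist was low in both mutants (4.63 and 4.68) and high in control samples 6 and 7 (10.69 and 10.33). At P13 it was high in both mutants (9.47 and 10.26) and in control sample 3 (10.31), not in control sample 4 (4.53). Among adults it was high in p53f/+ sample 3 (9.21) and low in the mutant without the p53 allele (4.48). The P20 count was 1453 genes, 638 higher and 815 lower: 2430 with the chip as a fixed block, 2511 as a random block and 1257 within chips (15 and 11 lists with the fixed block and within chips). It was 800 on chip F alone and 2599 on chip G, each with 1 mutant array. List means also differed by chip: on chip F and chip G the wound list differed by 3.49 and 4.01, the spinous and granular list by 0.35 and 1.13, the lipid barrier list by 0.06 and 0.60 and the melanocyte list by 0.56 and 1.22. The T and NK cell list differed by -2.25 and -0.90, the keratin-associated protein list by -1.57 and -0.34 and the fibroblast list by -1.76 and -0.06. The P20 count was 3282 without P20 control sample 3, 942 without control sample 5, 65 when only P20 arrays were fitted, and 429 with array weights. It was 434 with sex as a covariate, a setting added after the data were seen. Fitted on P20 arrays alone, 13 of 79 named genes stayed past the threshold. The SD of the log2 difference between 2 P20 arrays of a group was 1.07 to 1.11 across chips F and G, and 0.469 within chip G. At P3, P6 and P13 it was 0.317 to 0.547. The SEs given for P20 rest on the spread pooled over all groups, so they may be too small.

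**Figure D2:**
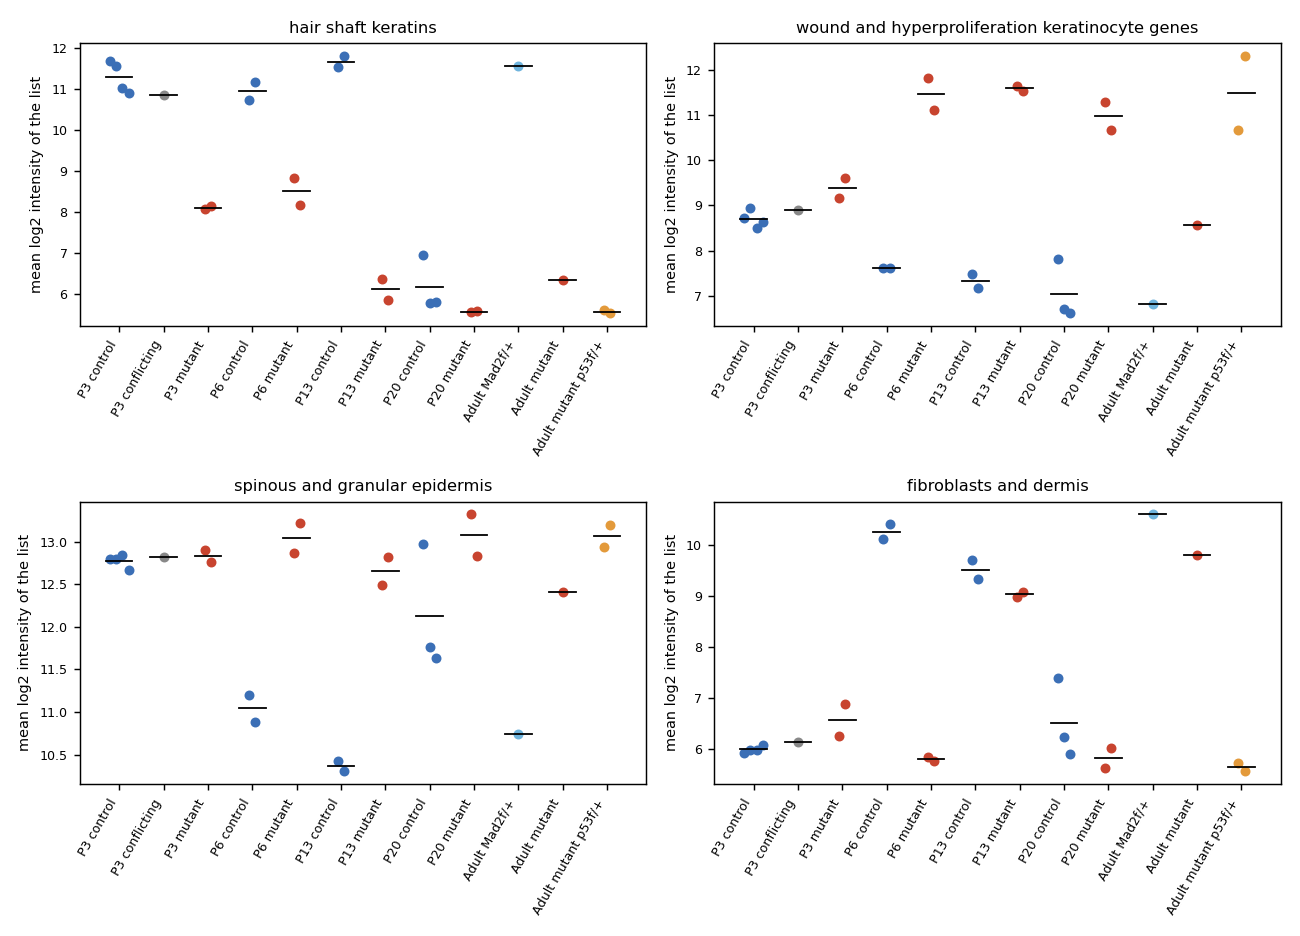
Mean normalized log2 intensity of 4 gene lists (panels) in each array (points, vertical axis) by group (horizontal axis), with group means as lines. Mutants lie below controls in the hair shaft keratin panel at P3, P6 and P13, above controls in the wound panel at each age, and the fibroblast panel shows 10.1 and 10.4 in the P6 controls against 5.77 and 5.84 in the P6 mutants.

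Averaged over P6, P13 and P20 (6 mutant against 7 control samples), 4653 genes passed, 1961 higher and 2692 lower. The largest rises among named genes were Sprr2d (8.51 ± 0.39), Lce3f (at least 125-fold) and Sprr2e (at least 76.5-fold). The largest falls were Krt33a (-4.75 ± 0.30), Krt15 (-4.59 ± 0.45), S100a3 (-4.52 ± 0.29) and Krt72 (at least 13.9-fold). Wound genes rose in 24 of 28, spinous and granular genes in 27 of 34 (2 fell), lipid barrier genes in 18 of 24 (2 fell; Alox12b at 2.51 ± 0.20, the lipid transporter Abca12 at 2.23 ± 0.78). Interferon genes rose in 20 of 23 (Bst2 at 2.47 ± 0.36), and cytokine genes in 16 of 23 (2 fell; Il33 at 3.84 ± 0.47). Falls covered 14 of 17 hair shaft keratins, 21 of 27 keratin-associated proteins, 10 of 14 inner root sheath genes (1 rose), 18 of 21 hair matrix genes (1 rose; Bmp4 at -2.92 ± 0.51). They also covered 13 of 17 follicle stem cell genes (1 rose), 11 of 18 mitosis genes (Mki67 at -1.52 ± 0.40, Top2a at -1.42 ± 0.33), 10 of 27 replication genes (Tyms at -1.49 ± 0.26), 8 of 20 repair genes (Parp1 at -1.34 ± 0.33) and 17 of 21 fibroblast genes (mean -1.87 ± 0.21). Both the fibroblast list (-4.45 at P6, -0.48 at P13 and -0.69 at P20) and the mitosis list (-1.80, -0.79 and -0.28) differed most at P6. Of 30 p53 targets 13 rose and 1 fell, with Polk at 1.54 ± 0.26, Phlda3 at 1.15 ± 0.14 and Sesn1 at -1.33 ± 0.20. Camera called 21 of 36 lists, 9 higher and 12 lower, and none with an estimated correlation. There the adjusted p was 0.0517 for wound, lipid barrier and hair matrix, 0.0542 for spinous and granular, hair shaft keratin and cytokine. It was 0.0582 for follicle stem cell and keratin-associated protein, 0.0726 for fibroblast, 0.0832 for inner root sheath and from 0.179 to 0.349 for the other 11 lists. The count was 1183 with the fibroblast covariate, a setting added after the data were seen, and within 1.5 times of 4653 in the other settings and with each array left out.

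**Figure D3:**
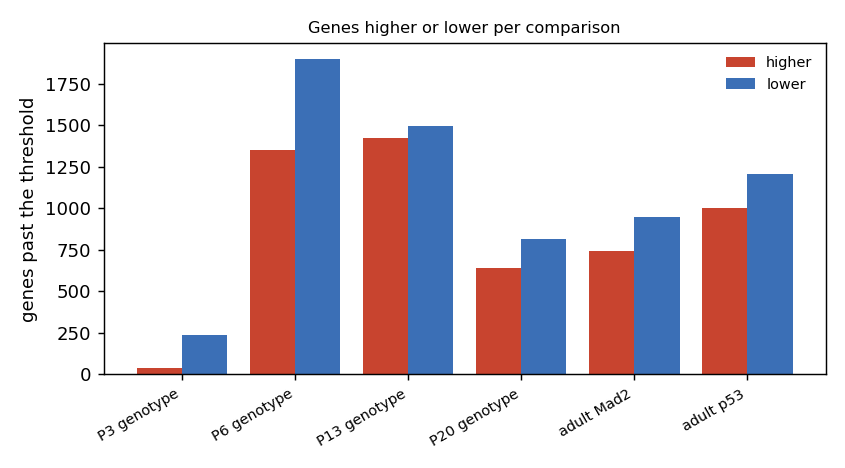
Number of genes past the threshold (vertical axis, from 0) that were higher (red) or lower (blue) in 6 comparisons (horizontal axis). The P3 bars stand at 40 and 237, and the tallest bar is the 1897 genes lower at P6.

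Whether the effect of P6 to P20 differed from that at P3 was tested directly as an interaction, and 932 genes passed, 508 with a more positive and 424 with a more negative difference at the later ages. Wound genes were the main group: 20 of 28 were more positive (22 adjusted over the list alone, with 1 more negative), with Sprr2d at 5.74 ± 0.72 and Lce3b at 5.48 ± 0.84. Spinous and granular genes (19 of 34, Lce1i at 4.31 ± 1.00) and lipid barrier genes (13 of 24, Lipn at 2.55 ± 0.41 and Alox12b at 2.40 ± 0.37) were more positive too, and 14 of 21 fibroblast genes more negative (Col6a3 at -4.78 ± 0.72). These 4 calls held with an estimated correlation. The fibroblast difference lay mainly at P6: the list differed by 0.57 at P3, -4.45 at P6, -0.48 at P13 and -0.69 at P20. Mitosis genes were more negative at the later ages (3 of 18, 9 adjusted over the list alone; Top2a at -2.22 ± 0.61, Ccnb1 at -2.09 ± 0.47), as were replication genes (3 of 27, Tyms at -1.82 ± 0.48) and follicle stem cell genes (2 of 17 with 1 more positive, Krt15 at -4.54 ± 0.83). The mitosis list differed by 0.46 ± 0.46 at P3, -1.80 ± 0.53 at P6, -0.79 ± 0.53 at P13 and -0.28 ± 0.48 at P20, so it was lowest at P6. Camera called the mitosis, replication and follicle stem cell lists with the preset correlation (adjusted p = 1.11e-06, 1.48e-05 and 0.00265). The adjusted p with an estimated correlation was 0.281 for each. Cytokine genes (7 of 23 more positive, Il18 at 2.74 ± 0.75) lost their call in the same way (adjusted p = 0.114 with an estimated correlation), as did the interferon list (1 of 23 more positive, Oasl2; adjusted p = 0.314 with an estimated correlation). Hair shaft keratins gave no call (adjusted p = 0.25): their median was -0.17 (0.05 with dim probes at their limits), their mean difference 0.32 ± 0.40, and camera's direction was up, so median and mean differed in sign. This does not show an equal effect at all ages. The list differed by -3.19 ± 0.34 at P3, -2.44 ± 0.39 at P6, -5.55 ± 0.39 at P13 and -0.61 ± 0.35 at P20, where it was low in controls too. The later ages thus lay on both sides of the P3 effect. The brighter Mad2l1 probe did not pass (-0.51, adjusted p = 0.62), while the dimmer one did (-1.09, adjusted p = 0.0438), though it could show no fall at P3 or P20, where it was undetected in controls too. The count was 1851 with the chip as a fixed block, 1950 as a random block, and 574 within chips. It was 432 without P3 mutant sample 1, 315 without P3 mutant sample 2 and 1903 without P20 control sample 3. With array weights it was 2440, and the balance turned to 1079 higher and 1361 lower, and with the conflicting array as a mutant it was 1408. In settings added after the data were seen it was 246 with the fibroblast covariate, 331 with sex as a covariate and 2231 without chips G and H. A further 10 lists passed with the preset correlation and not with the estimated one (adjusted p from 0.281 to 0.416 with an estimated correlation).

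Pairs of ages were also compared gene by gene. The effect at P6 differed from that at P3 in 1562 genes, at P13 in 1133 and at P20 in 506. Between later ages 1405 genes differed for P13 against P6, 1110 for P20 against P13 and 1250 for P20 against P6, and 3420 genes differed in at least 1 pair. Shared changes were counted against the overlap of independent lists, and no array was shared between ages. All ages did share 1 estimate of spread per gene, so the lists are not independent and the expected overlaps may be too low. P3 and P13 shared 191 lower genes where 24.6 would be shared by independent lists, and 16 higher genes (3.95). P6 and P13 shared 646 higher (133 for independent lists) and 528 lower genes (197), while 148 changed in opposite directions (327). At P6, P13 and P20 alike, 247 genes rose and 122 fell, and at all 4 ages 10 rose and 27 fell. The 10 included Krt16, Sprr2d, Fetub and Tlr2, a receptor for bacterial lipoproteins, and the 27 included Mad2l1, Krt32, Krt33a, Krt36, S100a3, Cux1, Sox9 and Cxcl12. Over all genes, which are not independent replicates, the correlation of log2 fold changes between 2 ages ran from r = 0.181 (P3 with P20) and 0.222 (P3 with P6) to 0.71 (P6 with adults). P6 and adults also shared the large fibroblast difference (-4.45 ± 0.37 and -3.57 ± 0.43).

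In adults, 3 mutants, 2 of them p53f/+, were compared with 1 Mad2f/+ control. The control side is a single array assumed to vary like the other groups, so this compares these arrays, not the genotypes, and rose and fell are meant in that sense. The fibroblast list differed by -3.57 ± 0.43, and the 2 p53f/+ mutants carried this: its mean was 10.60 in the control, 9.80 in the mutant without the p53 allele and 5.73 and 5.56 in the p53f/+ mutants. The hair fibre programme was again far lower in mutants: 15 of 17 hair shaft keratins fell, with Krt34 at -9.06 ± 1.11, Krt81 at -8.90 ± 0.87 and Krt33a at -8.82 ± 0.62. So did 25 of 27 keratin-associated proteins (26 adjusted over the list alone; Krtap7-1 at -9.16 ± 0.86) and 9 of 14 inner root sheath genes (Krt71 at -8.97 ± 0.97, Krt27 at -8.45 ± 1.12; 2 others rose). Falls also covered 10 of 21 hair matrix genes (17 adjusted over the list alone; Hoxc13 at -3.99 ± 0.64) and 8 of 17 follicle stem cell genes (Krt15 at -4.61 ± 0.93, Sox9 at -2.77 ± 0.33). Wound genes rose in 18 of 28, with the stefin gene Stfa1 at 7.43 ± 0.58, Defb14 at 7.25 ± 0.66, S100a9 at 6.72 ± 1.19 and Sprr2d at least 311-fold higher. The wound rise was larger in the p53f/+ mutants, whose list mean lay 2.94 ± 0.60 above that of the other mutant. All 3 mutants together lay 3.70 ± 0.57 above the control. Spinous and granular genes rose in 21 of 34 (Lce1f at 5.47 ± 1.22, Lce1d at 4.73 ± 0.90) and lipid barrier genes in 13 of 24 (Alox12b at 4.24 ± 0.42, Aloxe3 at 3.12 ± 0.39). Fat cell genes fell in 7 of 8, such as Cfd (-5.05 ± 0.66) and the leptin gene Lep (-4.33 ± 0.50), and fibroblast genes in 18 of 21, such as Lum (-6.24 ± 0.83). The fat cell fall too was carried by the p53f/+ mutants (list mean 6.01 and 5.67, against 10.01 in the other mutant and 10.91 in the control). These 10 lists were called by camera with the preset (adjusted p from 1.31e-36 to 2.19e-06) and the estimated correlation.

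A further 9 lists were called with the preset correlation and not with the estimated one. Melanocyte genes (9 of 14 fell, Tyrp1 at -2.91 ± 0.86) and endothelium and blood genes (9 of 14 fell, Egfl7 at -3.39 ± 0.79) were lower, as were mitosis (3 of 18 fell, Ccnb1 at -1.72 ± 0.52), replication (3 of 27 fell, Uhrf1 at -2.05 ± 0.46) and checkpoint genes (3 of 17 fell, Spc25 at -1.72 ± 0.43) (adjusted p = 0.0592, 0.0958, 0.466, 0.303 and 0.365 with an estimated correlation). Cytokine (8 of 23 rose, 1 fell; Il18 at 3.58 ± 0.84), cholesterol synthesis (3 of 20 rose; Mvk at 1.92 ± 0.31), T and NK cell (4 of 13 rose; Cd3e at 1.99 ± 0.61) and interferon genes (2 of 23 rose; Stat2 at 1.71 ± 0.52) were higher (adjusted p = 0.0958, 0.275, 0.487 and 0.544 with an estimated correlation). The endothelium and cholesterol synthesis differences lay in the p53f/+ mutants alone: the mutant without the p53 allele stood at 9.10 and 8.14 in these lists, the control at 8.38 and 8.18. The count was 1692 genes, 744 higher and 948 lower, with 19 of 36 lists (21 with the chip as a fixed block and within the chip). It was 2655 with the chip as a fixed block, 2733 as a random block, and 1078 within the chip. Fitted on adult arrays alone it was 153, with 34 of 104 named genes still past the threshold. It was 2687 with array weights, and it was 2898 without chips G and H and 170 with the fibroblast covariate, both settings added after the data were seen.

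The p53 comparison set the 2 adult p53f/+ mutants against the single adult mutant without that allele. That array is assumed to vary like the other groups, so this compares these arrays, not the p53 genotypes, and rose and fell are meant in that sense. Trp53 itself averaged 7.50 ± 0.75 (SD, n = 2) against 8.87, a difference of -1.37 ± 0.76 (SE, adjusted p = 0.27). Transcripts of muscle, fat, dermis and blood vessels were far lower in the p53f/+ samples: 11 of 15 muscle genes fell (Atp2a1, the fast-muscle calcium pump, at -9.51 ± 0.98; the actin gene Acta1 at least 397-fold lower). So did 6 of 8 fat cell genes (Lpl at -5.08 ± 0.60), 17 of 21 fibroblast genes (Dcn at least 308-fold lower; 1 other rose) and 9 of 14 endothelial and blood genes (Hba-a1 at -5.05 ± 1.38). The muscle, fat and fibroblast calls held with an estimated correlation, and the endothelium call did not (adjusted p = 0.0522 with an estimated correlation). Wound genes were higher in 16 of 28 (18 adjusted over the list alone), with Krt6b at 6.47 ± 0.98, Sprr2e at 6.20 ± 0.72 and Sprr1b at 5.29 ± 0.69. So were 9 of 34 spinous and granular genes, a list in which Krt2 fell (-5.01 ± 0.54). Cholesterol synthesis (7 of 20 rose, Cyp51 at 2.53 ± 0.42), lipid barrier (7 of 24 rose, 1 fell; Cers3 at 3.40 ± 0.35, Fa2h at -3.46 ± 1.02) and antioxidant genes (6 of 19 rose, 1 fell; Gsta4 at 3.69 ± 0.90) were higher by camera. Follicle stem cell genes were lower (5 of 17 fell; Ccn2 at -4.64 ± 0.68). The calls for wound, spinous and granular, cholesterol synthesis, lipid barrier, antioxidant and stem cell genes were lost with an estimated correlation (adjusted p = 0.197, 0.762, 0.245, 0.245, 0.459 and 0.398). Of 30 p53 targets 4 rose and 1 fell, with Sesn2 at 1.91 ± 0.33 and Ei24 at 1.19 ± 0.35, and no camera call (adjusted p = 0.509; median -0.01, mean 0.12 ± 0.14 and camera's direction up, so the median differed in sign). The count was 2205 genes, 1000 higher and 1205 lower: 3593 with the chip as a fixed block, and 3553 as a random block. It was 1409 without p53f/+ sample 3, 177 when only the compared arrays were fitted and 10 with the fibroblast covariate, a setting added after the data were seen. It was 4310 without chips G and H, also added then. Within the chip that holds both genotypes, 1 array against 1, it was 1695.

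Among the 11 control samples, 6415 genes differed over P3, P6, P13 and P20 (F test over 3 contrasts), 4757 between P6 and P3, 3664 between P13 and P3, and 2619 between P20 and P3. Hair fibre genes were low in P20 controls. Krt33a averaged 14.74 ± 0.50 (SD, n = 4) at P3, 15.14 ± 0.25 (SD, n = 2) at P13 and 7.29 ± 0.94 (SD, n = 3) at P20. The mean of the hair shaft keratin list differed from P3 by -0.35 ± 0.34 (SE) at P6, 0.37 ± 0.34 at P13 and -5.11 ± 0.30 at P20. The stem cell keratin Krt15 was at 14.11 ± 0.19 (SD, n = 3) in P20 controls and at 11.28 ± 1.13 (SD, n = 4) in P3 controls. The T and NK cell list differed from P3 by 2.04 ± 0.29 at P20, and Cd3e was at 10.24 ± 0.35 (SD, n = 3). The fibroblast list mean was higher than at P3 by 4.27 ± 0.32 at P6, 3.52 ± 0.32 at P13 and 0.52 ± 0.28 at P20. That of mitosis genes was higher than at P3 by 1.77 ± 0.46 at P6 and 1.40 ± 0.46 at P13, and differed by 0.09 ± 0.40 at P20. No list test was planned for this comparison, and the ages lay on different chips, so age and chip cannot be told apart. With the chip as a random block 3848 genes passed, with the fibroblast covariate 2689 and with array weights 11898.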

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

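All tests of explanations in this part were chosen after the results were seen, except the correlation of the adult p53 difference with the P6 effect and the splits of the samples within ages.

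Among the 4 P3 controls, 1 array stood far from the other 3 in the mean of 3 cell type lists: the gap to the nearest array made up 0.963 of the range for myeloid cells (control sample 7), 0.953 for melanocytes (control sample 5) and 0.915 for Merkel cells and nerve (control sample 7). These were 3 of 39 values tested, and chance alone singles out about 1 in 20.

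The genotype effect differed between ages by the interaction test. The mean effect of P6 to P20 differed from the P3 effect in 932 genes, and between pairs of ages the effect differed in 1562 genes (P6 against P3), 1133 (P13 against P3), 506 (P20 against P3), 1405 (P13 against P6), 1110 (P20 against P13) and 1250 (P20 against P6). In the later ages minus P3, camera called 19 lists at the preset correlation, and of these only the wound, spinous and granular, lipid barrier and fibroblast calls held with an estimated correlation. The 19 lists had a median log2 difference of 3.76 for wound genes, 1.61 for spinous and granular, 1.29 for Langerhans, 1.21 for lipid barrier, 1.20 for interferon, 1.19 for cytokine, 1.15 for sebaceous, 0.85 for keratin-associated protein and 0.59 for cholesterol synthesis genes. The negative medians were -2.21 for fibroblasts, -1.43 for mitosis, -1.32 for endothelium and blood, -1.05 for follicle stem cells, -0.81 for hair matrix, -0.76 for replication, -0.66 for checkpoint, -0.63 for melanocyte, -0.57 for DNA repair and -0.24 for ribosomal protein genes.

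Hair shaft keratin genes were lower in mutants, and more dermis and deep follicle in the control samples could give the same difference. At P3 the hair list differed by -3.19 ± 0.34 (SE) while the fibroblast list was higher in mutants (0.57), which argues against dermis in the controls at that age. At P13 the hair list fell below the fibroblast list by -5.07 ± 0.35, with fibroblasts at -0.48, and this too argues against it. At P6 the hair list fell less than the fibroblast list (difference 2.01 ± 0.35, fibroblasts -4.45), so loss of hair genes and dermis in the controls cannot be told apart by this test. In controls the fibroblast list was higher at P6 than at P3 by 4.27 ± 0.32, while the hair list differed by -0.35 ± 0.34. That comparison crosses ages and chips, so it does not settle the question. Sex is argued against at P6, where the difference was -2.44 ± 0.39 and 0 arrays had high Xist. Fibroblast genes do not measure deep follicle recovered without dermis. Uneven recovery of follicles was therefore not tested and stays open at each age, as does the Mad2 deletion as a hypothesis.

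Wound and hyperproliferation genes were higher in mutants, which a smaller share of dermis could bring about by raising all epidermal genes alike. At P6 epidermal lists did not move alike: the basal list differed by -1.21 ± 0.76 (SE) and the spinous and granular list by 2.00 ± 0.35, and the wound list lay above their mean (0.39) by 3.47 ± 0.70. At P13 these were 0.42 ± 0.76 and 2.29 ± 0.35, and the wound list lay above their mean (1.35) by 2.91 ± 0.70, which argues against an equal rise of all epidermal genes, although the spinous and granular list rose with the wound list. At P13 the keratin, Sprr and Lce3 members rose beyond the myeloid list by 3.93 ± 0.31 (myeloid list 1.22). These members were picked as genes that myeloid cells do not express, and their rise was known before the test. The outcome was thus fixed in advance, and it decides nothing about infiltrating myeloid cells as a source. The other members, such as S100a9 and Stfa2, were not covered, and myeloid cells as their source stay open. A response of keratinocytes to the Mad2 deletion or to the loss of hair stays open, and these were not separated.

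Genes that differed with p53 dose in adult mutants may reflect dermis and muscle in the single array without the p53 allele. The differences correlated with the P6 effect, with which they share no array, at r = 0.631, and the fibroblast list differed by -4.15. The p53 target list differed by 0.12 ± 0.14 (SE), so an effect of the p53 dose itself cannot be told apart from none here, with 1 array on one side.

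For the mean effect of P6 to P20, 100 of 360 splits of the arrays within ages were drawn, and 2 of them, the real one included, gave as many genes as the real 4653. The highest of the others gave 5519. In it all arrays but P20 control sample 3 had changed sides, and other splits gave 3406, 3385 and 3314 genes. Genes were counted in either direction, so exchanging nearly all sides repeats most of the real contrast with its sign turned. The splits with 3406 and 3385 genes had 1 and 3 arrays on their real side, and that with 3314 had 9. Why the split with 3314 called so many genes was not tested. The drawn splits exchanged P6 and P20 arrays between chips, and arrays of a chip are correlated (0.472). With exchanges only within chips, 100 of 108 splits were drawn, 1 of them, the real one, gave as many genes, and the highest of the others gave 3217. Both shares are under 0.05, so chance alone is unlikely to give the real count, but these counts do not exclude it.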

How the results depend on the processing

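The fibroblast and sex covariates, the fits without chips G and H or on 1 P20 chip, and all settings for pairs of ages were chosen after the results were seen. No Mad2l1 difference changed its sign. Named genes past the threshold did change sign with the fibroblast covariate: 29 of 136 at P6, 21 of 95 for adult p53, 12 of 104 for adult Mad2, 10 of 141 for the mean of P6 to P20 and 5 of 71 for its difference from P3. With the mean of a gene's probes 1 turned at P6 and 1 in the mean of P6 to P20. With other settings 137 counts of genes stayed within 1.5 times of their value and 51 moved further, 69 counts of lists stayed and 11 moved, and the Mad2l1 difference kept its side of the threshold in 145 cases, lost it in 14 and gained it in 1. No paired analysis was possible because mutants and controls of an age share no replicate numbers. The chip, which mutants and controls share in part, was used as a block instead. Mice were killed at each age, so samples of different ages came from different mice, while within an age the labels do not say so. The cause was not tested for any value below, except where fewer arrays were fitted. Dim genes are limited by signal over background, and the arrays by their number.

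With the chip as a fixed block the counts were 421 (85 higher, 336 lower) at P3, 4494 at P13, 2430 at P20, 1851 for P6 to P20 minus P3, 2655 for the adult Mad2 and 3593 for the adult p53 comparison and 5472 for any pair of ages, against 277, 2913, 1453, 932, 1692, 2205 and 3420. With the chip as a random block (correlation 0.472) they were 436, 4401, 2511, 1950, 2733, 3553 and 5798, and 3848 against 6415 over the control ages. Within chips they were 1704 at P6 (3248 with all), 574 for P6 to P20 minus P3, 1078 for adult Mad2 and 2219 for any pair, and Mad2l1 at P6 was at -1.91 (adjusted p = 0.0626). With only the compared groups the counts were 6002 at P6, 4894 at P13, 65 at P20 (45 higher, 20 lower), 153 for adult Mad2 (24 higher, 129 lower) and 177 for adult p53 (6 higher, 171 lower), and Mad2l1 was at -2.06 (adjusted p = 0.198) at P20 and -3.16 (adjusted p = 0.058) in adults.

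With the conflicting array counted as a mutant, P3 had 70 genes, P6 to P20 minus P3 had 1408, and Mad2l1 at P3 was at -1.34 (adjusted p = 0.479). Of 34 named P3 genes, 6 then stayed past the threshold, against 30 with that array as a control. With array weights the counts were 456 at P3, 6546 at P6, 5570 at P13, 429 at P20, 2440 for P6 to P20 minus P3 (1079 higher, 1361 lower, against 508 and 424), 2687 for adult Mad2, 11898 over the control ages and 7264 for any pair, with Mad2l1 at P20 at -2.36 (adjusted p = 0.136). In the authors' normalized values Mad2l1 was at -0.72 (adjusted p = 0.131) at P3 and -0.64 (adjusted p = 0.0714) at P20. The dimmer Mad2l1 probe alone gave -0.11 (adjusted p = 1) at P3, -0.24 (adjusted p = 0.676) at P20 and -1.09 (adjusted p = 0.0438) for P6 to P20 minus P3. That probe was below detection in every P3 and P20 array, so its P3 and P20 values are fixed by background and test nothing. The third value also rests on the P6 and P13 controls, where the probe was detected, and it passed where the brighter probe did not (-0.51, adjusted p = 0.62). With detection in at least 12 arrays the adult counts were 1275 (693 higher, 582 lower) for Mad2 and 1554 (926 higher, 628 lower) for p53, against 744 higher and 948 lower, and 1000 higher and 1205 lower.

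Lists past camera with an estimated correlation numbered 5 at P3 (12 with the preset one), 3 at P6 (27), 7 at P13 (15), 0 at P20 (12), 0 for the mean of P6 to P20 (21), 4 for its difference from P3 (19), 10 for adult Mad2 (19) and 3 for adult p53 (10). With fry they numbered 6 at P3, 28 at P6, 17 at P13 and 7 at P20. Fry called 28 for the mean of P6 to P20, 15 for its difference from P3, 17 for adult Mad2 and 11 for adult p53.

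With the fibroblast covariate the counts were 69 at P6 (56 higher, 13 lower), 1183 for the mean of P6 to P20, 246 for its difference from P3, 170 for adult Mad2, 10 for adult p53 and 2689 over the control ages. At P6 17 lists passed, and Mad2l1 was at -3.90 (adjusted p = 0.249) at P6 and -4.52 (adjusted p = 0.125) in adults, where list and genotype nearly coincide. With sex as a covariate the counts were 434 at P20 and 331 for P6 to P20 minus P3, with Mad2l1 at P20 at -2.08 (adjusted p = 0.0578). Without chips G and H they were 514 at P3, 5574 at P6, 5228 at P13, 2231 for P6 to P20 minus P3, 2898 for adult Mad2, 4310 for adult p53 and 6995 for any pair, with Mad2l1 at P20 at -1.71 (adjusted p = 0.112). The P20 arrays of chip F alone, 1 mutant and 1 control, gave 800 genes (Mad2l1 -1.71, adjusted p = 0.121), and those of chip G, 1 mutant and 2 controls, 2599.

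Leaving out 1 array of the compared groups at a time, where a lone array left in a group is assumed to vary like the other groups, gave 139 to 272 genes at P3, 1762 to 2092 at P6, 1361 to 2202 at P13, 942 to 3282 at P20, 315 to 1903 for P6 to P20 minus P3, 2196 to 5508 for any pair and 1409 to 2070 for adult p53, and 7 to 15 lists at P3 and 7 to 16 at P20. Mad2l1 ranged from -2.63 to -1.66 at P3 (adjusted p = 0.184 without mutant sample 1) and from -2.42 to -1.71 at P20 (adjusted p = 0.0502 without mutant sample 1). The mean of P6 to P20 ranged from 3753 to 5908 genes and adult Mad2 from 1294 to 2423. Leaving out an array of another group gave 245 to 325 genes at P3, 2964 to 3969 at P6, 2711 to 3691 at P13, 1266 to 1597 at P20, 4447 to 4748 for the mean of P6 to P20 and 932 to 1052 for its difference from P3. It gave 1492 to 2275 for adult Mad2, 1948 to 2865 for adult p53 and 3420 to 3604 for any pair. Not run were the fixed block and the within-chip fit for the control ages, the authors' values for adults, and adult comparisons without a group's single array.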

Other observations

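The hair cycle test in this part was chosen after the result was seen.

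In the antioxidant list, 2 of 5 glutathione transferase genes, Gsta1 and Gsta4, rose at P6, P13 and P20, and Gsta2, Gstm1 and Gstp1 did not pass the test at these ages. Gsta4, whose enzyme detoxifies lipid peroxidation products, rose by 3.15 ± 0.73 (SE) at P6, 5.22 ± 0.73 at P13 and 2.95 ± 0.67 at P20, and Gsta1 rose by 3.08 ± 0.61, 3.83 ± 0.61 and 2.57 ± 0.56. The list as a whole gave no camera call at P6 (4 of 19 rose, 2 fell; adjusted p = 0.263), P13 (3 rose, 3 fell; adjusted p = 0.558) or P20 (5 rose; adjusted p = 0.0501).

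In the senescence list, Lmnb1, a lamin of the nuclear envelope, differed by -2.26 ± 0.33 (SE) at P6 and -2.26 ± 0.38 in adults, and Igfbp7, a secreted growth factor binding protein, by -4.48 ± 0.55 and -3.60 ± 0.64. The fibroblast list differed by -4.45 ± 0.37 and -3.57 ± 0.43 in the same comparisons. Igfbp7 did not pass the test at P13 or P20. The list gave no camera call at P6 (2 of 11 rose, 3 fell; adjusted p = 0.341) or in adults (1 rose, 4 fell; adjusted p = 0.0763).

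Melanocyte genes went different ways with age. The list mean differed between mutants and controls by 0.19 ± 0.25 (SE) at P3, -1.28 ± 0.29 at P6, -1.01 ± 0.29 at P13, 1.03 ± 0.26 at P20 and -1.90 ± 0.33 in adults. The camera calls at P6, P13, P20 and in adults were lost with an estimated correlation (adjusted p = 0.243, 0.368, 0.32 and 0.0592). In controls the list lay above P3 by 1.89 ± 0.25 at P6 and 1.63 ± 0.25 at P13, and differed from P3 by -0.93 ± 0.22 at P20. The fibroblast list moved the same way in part: it differed by -4.45 ± 0.37 at P6 and -3.57 ± 0.43 in adults, and in controls lay above P3 by 4.27 ± 0.32 at P6 and 3.52 ± 0.32 at P13.

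The P3 array with a mutant genotype label and a control type label had a Mad2l1 log2 intensity of 7.69. Of the 277 genes past the threshold at P3, it lay within the range of the controls in 145 and within that of the mutants in 4. Its median position was 0.191, where 0 is the control mean and 1 the mutant mean. Its hair shaft keratin list mean was 10.9 and its fibroblast list mean 6.14.

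Hair shaft keratin genes were low in P20 controls, and a hypothesis is that these controls were in a resting phase of the hair cycle. The test was whether another compartment of the growing hair moved with them: from P13 to P20 controls the hair shaft keratin list differed by -5.49 ± 0.35 (SE) and the inner root sheath list by -4.57. A change in hair cycle phase would give this, but so would less deep follicle in the P20 samples, and the test cannot separate the 2. In the same controls the fibroblast list lay above P3 by 3.52 ± 0.32 at P13 and by 0.52 ± 0.28 at P20. Age and chip are also confounded in this comparison, and no phase was recorded in the labels used here.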
